A study of Mus musculus with 6 samples.

How the data were processed

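Gene expression was measured in B16 cells, a mouse melanoma line, on 6 Affymetrix arrays, 1 per group, from biotin-labelled cRNA made from 5 µg of total RNA. Per the labels, cells were put in serum-free medium 2 h before the exposure. They were then kept for 3 h in normoxia, for 3 h in chronic hypoxia (less than 1% oxygen), or through 3 periods of 1 h of hypoxia interrupted by 30 min of reoxygenation (cyclic hypoxia). Each regime was collected at the end of the exposure and 1 h later, the last hour being reoxygenation for the hypoxic cells. The labels do not say that the normoxia controls were matched to the longer total time of the cyclic regime.

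The deposited values are signals (intensity units) on a linear scale for 22690 probe sets, 1 column per array. The submitters' processing notes name GCOS, and neither its version nor its algorithm is given. The trimmed mean of every column, leaving out 2% at each end, was 100 to 3 significant digits, so the authors' scaling was kept and the values were used as deposited. No detection calls were used here. Array signals carry no counts, so precision was limited by the number of arrays and, for dim genes, by signal over background. With 1 array per group a difference between 2 arrays has no error of its own.

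Values under the 20th percentile of all values (2.10 units, the floor) were set to it before taking log2. Probe sets with a mean signal under the 40th percentile of the means (8.33 units) and the 64 control probe sets were left out, which left 13556 probe sets. Probe sets were matched to genes by Entrez identifier. There were 20393 that named 1 gene, 691 that named several and 1606 that named none, and current symbols were found for 20364. For gene counts and lists, each of 7746 genes was represented by its probe set with the highest mean signal.

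Each hypoxia array was set against the normoxia array of the same collection, cyclic against chronic hypoxia at each collection, and the second collection against the first within each regime. These contrasts of single arrays were described by counts of genes 2-fold or more higher or lower, without a test. Because chronic and cyclic hypoxia share their normoxia array, 100 simulated sets of unchanged arrays with the spread between the 2 normoxia arrays gave the overlap that a shared control brings alone. The overlap of independent calls was computed from the counts.

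Tests used limma 3.58.1 in R 4.3.3, with moderated two-sided tests, an intensity trend, and Benjamini-Hochberg adjustment over the 13556 probe sets at 0.05. An additive fit held regime and collection (2 residual degrees of freedom), so that the 2 collections stood in for replicates and a gene that returned in the last hour counted as noise. An interaction fit let the hypoxia effect differ between collections (1 residual degree of freedom), with chronic and cyclic hypoxia standing in for replicates. On 10 simulated data sets with 200 changed probe sets each among 13556, the additive fit of mean hypoxia recovered 80.4% of log2 changes of 1 and 98.8% of log2 changes of 2, with 6.3 false calls per data set. The additive chronic contrast recovered 71.9% and 97.6%, with 5.9 false calls. The interaction fit at the end of hypoxia recovered 53.6% and 97.2%, with 31 false calls. Each simulated change was equal in all 4 hypoxia arrays, and the noise was that between the normoxia arrays. In the data, differences between regimes and collections enter the residual. The SD of all differences was 0.39 between the normoxia arrays and 0.71 for cyclic hypoxia with reoxygenation. The shares recovered therefore do not give the power in the data, and few calls need not mean few changes.

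There were 21 gene lists with 428 genes in all, fixed before the data were examined along with the comparisons, the floor, the filter and the rule for named genes. They covered HIF-regulated glycolysis, other HIF targets, immediate-early genes, heat shock chaperones, the unfolded protein and integrated stress response, NRF2 and antioxidant genes, melanocyte lineage and pigment genes, cell cycle genes, invasion and metastasis genes, angiogenic factors, oxidative phosphorylation, oxygen-dependent histone demethylases, sterol synthesis, NF-kB and inflammatory genes, interferon-stimulated genes, p53 targets and housekeeping genes, and markers of fibroblasts, immune cells, endothelium and keratinocytes. Of the listed genes, 39 were not named on the array under any symbol found. In each array contrast a list was described by its median and by that median's percentile among 10000 random lists matched on mean signal. In the additive fit, lists with at least 5 genes were tested with camera at a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry. Counts of members are given over all probe sets and adjusted over the list alone.

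The genes named in the text were the 10 highest and 10 lowest in both hypoxia arrays at each collection, and the 6 highest and 6 lowest for cyclic against chronic hypoxia. They also included 8 each for the last hour, 4 each between the normoxia arrays, up to 5 genes per direction in each fit, up to 4 members per list and comparison, and a short fixed set of genes. Ranks used the smaller of the 2 differences, both sides above the floor and the higher side at or above the 60th percentile of all values (35.8 units). Members named for a call adjusted over the list alone, and genes named for the smallest adjusted p of a contrast without calls, were chosen after their values were seen.

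Alternatives were quantile normalization, median centring, other floors, a pseudocount, other filters, the mean of a gene's probe sets, moderation without trend or robust, no collection term, each array left out, and other probe sets of each named gene. An analysis of genes with a mean signal of at least 100 and the removal of a trend on genomic gene length were chosen after seeing the data. Gene lengths came from the RefSeq annotation of the mouse GRCm38.p6 assembly. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.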

Results

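The series asks how low oxygen, given steadily or in cycles, alters the transcriptome of B16 melanoma cells, and its title links this to metastatic potential. There were 6 arrays, 1 each for normoxia, chronic hypoxia and cyclic hypoxia, collected at the end of the exposure or 1 h later, so no group had a replicate. The median signal of an array lay between 15.9 (after cyclic hypoxia and reoxygenation) and 19.3 units (after chronic hypoxia and reoxygenation), with the same trimmed mean of 100. The floor took in 18.4% to 21.2% of the values of an array. The array after cyclic hypoxia and reoxygenation had the lowest mean correlation with the other arrays, 0.940 across genes (which are not independent replicates), and the other means were 0.962 to 0.967.

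At the end of hypoxia, genes of glucose use stood well above normoxia in both hypoxic arrays, and further in chronic than in cyclic hypoxia. Hk2 (hexokinase 2, the first step of glycolysis) had a signal of 165 in normoxia, 1279 after chronic hypoxia and 534 after cyclic hypoxia, log2 differences of 2.95 and 1.69. Pdk1, a kinase that restrains the entry of pyruvate into mitochondria, differed by 2.61 and 1.74. Slc2a1, the glucose transporter GLUT1, differed by 2.38 and 1.34, and the phosphofructokinase Pfkp by 1.68 and 1.07. Of 18 measured glycolysis genes regulated by HIF, the hypoxia-inducible transcription factor, 7 were at least 2-fold higher after chronic and 4 after cyclic hypoxia, with medians of 0.60 and 0.36. Their percentiles among the random lists were 100 and 99.98.

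The other HIF targets followed the same order. Of 31 measured members, 17 were at least 2-fold higher after chronic hypoxia (median 1.22) and 6 after cyclic hypoxia (median 0.39, with 1 member lower). Bnip3, a mitophagy receptor, differed by 2.66 and 1.38, Maff (a small Maf transcription factor) by 2.26 and 2.01, and the histone demethylase Kdm3a by 1.60 and 1.67. Stc1, which encodes a secreted glycoprotein, was below the floor in normoxia and is given against it, at least 4.21 and 1.87 higher on the log2 scale. Nfil3, a bZIP repressor, differed by 2.75 and 1.69, but also by 1.74 between the normoxia arrays, at 4.73 units in normoxia. Among the fixed genes, Vegfa (vascular growth factor) differed by 0.92 and 0.33, Egln1 (a prolyl hydroxylase that marks HIF for degradation) by 1.26 and 0.39, Ndrg1 by 0.94 and 0.99, and Ddit4 (an inhibitor of mTORC1) by 1.23 and 0.27. Hif1a itself differed by -0.09 and -0.31.

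**Figure D1:**
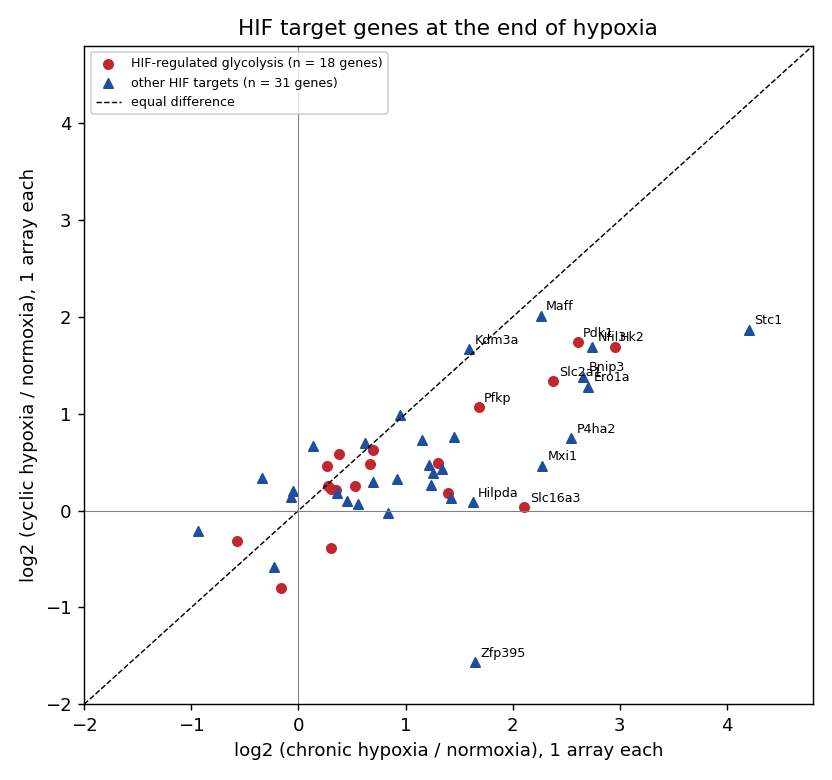
Log2 difference from normoxia at the end of hypoxia of each measured HIF target, chronic hypoxia on the x axis and cyclic hypoxia on the y axis, 1 array per side; circles are the 18 glycolysis genes and triangles the 31 other targets. Most points lie below the line of equal difference, Hk2 at 2.95 and 1.69 among them.

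Genes outside the HIF lists shared the top ranks. Ak4, a mitochondrial adenylate kinase, went from 13.0 units in normoxia to 259 and 55.7, log2 differences of 4.31 and 2.10. Rassf1 (a Ras-association scaffold) differed by 1.94 and 2.09, Gtpbp2 (a ribosome rescue GTPase) by 2.24 and 1.77, Akap8l by 1.52 and 1.65, Mt2 (a metal-binding metallothionein) by 1.48 and 1.54, and Herpud1, a component of endoplasmic reticulum-associated degradation, by 1.48 and 1.59. The lowest were Abcb1b (a drug efflux transporter; -1.91 and -2.15), Ccne2 (cyclin E2; -1.89 and -2.16), Csgalnact2 (-1.78 and -1.80), Mrpl33 (a mitochondrial ribosomal protein; -1.71 and -1.67), Pkia (an inhibitor of protein kinase A; -1.72 and -1.60) and Prokr1 (-1.83 and -1.54). They were followed by Zfp326 (-1.54 and -1.42), Itgb3bp (-1.40 and -1.72), Zfp931 (-1.39 and -2.16) and Sgms1 (-1.50 and -1.37, with 0.30 at another probe set after cyclic hypoxia). The normoxia arrays also differed at these genes. Of the higher genes, Mt2 differed between them by 0.89, Rassf1 by 0.89 and Herpud1 by 0.59. The lower genes all had a higher signal in the first normoxia array, which is their control. The differences were -1.20 for Mrpl33, -1.15 for Sgms1, -1.10 for Pkia, -1.01 for Zfp326, -0.88 for Zfp931, -0.86 for Abcb1b, -0.77 for Itgb3bp, -0.71 for Prokr1, -0.70 for Csgalnact2 and -0.11 for Ccne2.

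**Figure D2:**
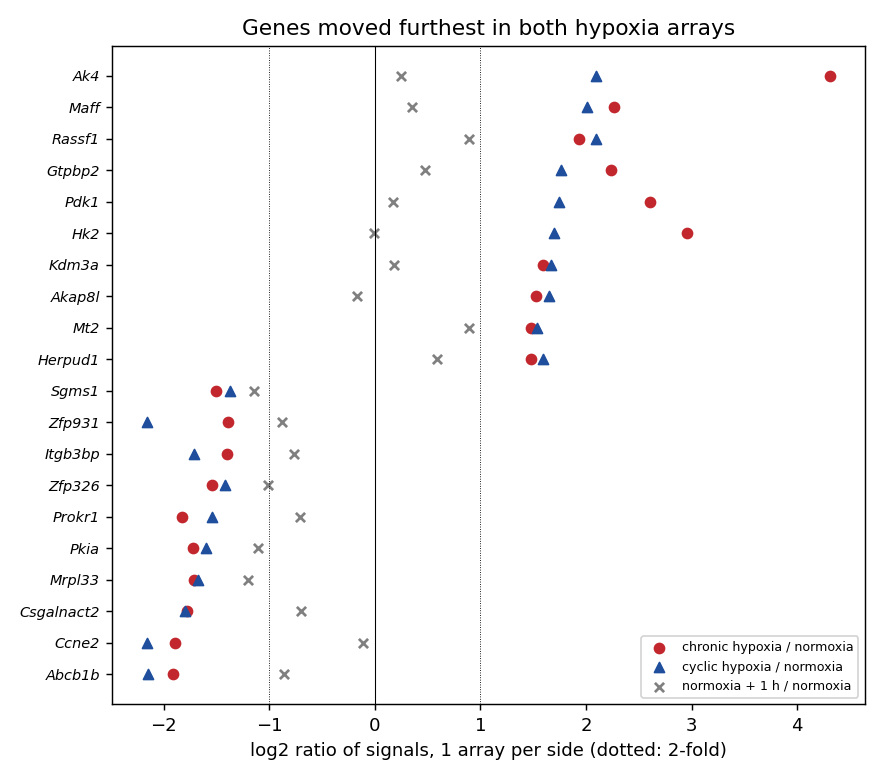
Log2 ratios to normoxia of the genes ranked highest and lowest in both hypoxia arrays at the end of hypoxia, with the ratio of normoxia plus 1 h to normoxia as grey crosses; each point is 1 array over 1 array. The crosses of most lower genes, such as Mrpl33 at -1.20, also lie left of 0.

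In all, 196 genes were 2-fold or more higher and 183 lower after chronic hypoxia, and 164 higher and 421 lower after cyclic hypoxia. Quantile normalization gave 205 higher and 327 lower after cyclic hypoxia. The normoxia arrays themselves differed by this much at 67 genes higher and 145 lower, or 86 and 101 with quantile normalization. Nearly all of these were dim. Among 3573 genes with a mean signal of at least 100 the normoxia arrays differed at 0 higher and 1 lower, against 52 higher and 14 lower after chronic and 37 higher and 52 lower after cyclic hypoxia. Both hypoxia arrays were 2-fold higher at 71 genes and lower at 74, and opposite at 5. Independent calls would give 4.15 and 9.95, and the simulation of a shared control 29.4 and 31.0. The covariance across genes was 0.17, and 0.07 when simulated, and part of the overlap may come from the shared normoxia array. Without a common array, chronic hypoxia at the end and cyclic hypoxia 1 h later agreed at 36 higher and 27 lower genes, with 57 opposite. Independent calls would give 6.98 and 19.4. For cyclic hypoxia at the end and chronic hypoxia 1 h later these were 29, 12 and 43, against 4.89 and 4.73. The correlations were 0.07 and 0.03, against 0.58 with the shared array. These contrasts also cross the collections, so a change in the last hour may lower agreement.

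**Figure D3:**
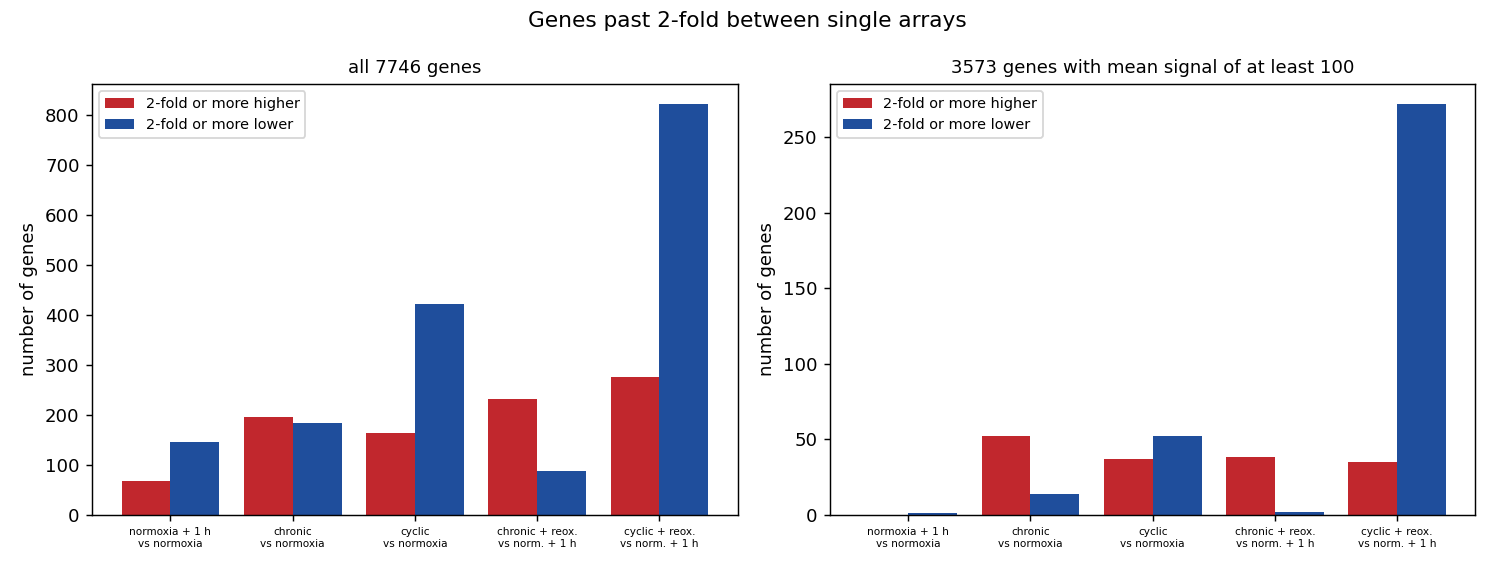
Number of genes 2-fold or more higher (red) or lower (blue) between single arrays, for all 7746 genes (left) and the 3573 with a mean signal of at least 100 (right). Among the brighter genes the normoxia arrays differ at 1 gene, and 272 are lower after cyclic hypoxia and reoxygenation.

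The additive fit asks what held at both collections, and for mean hypoxia it called 2 genes. Over chronic and cyclic hypoxia together, Hk2 rose by 2.10 (SE 0.167, adjusted p = 0.0207) and Bnip3 by 1.94 (SE 0.190, adjusted p = 0.0488), each higher than its control in 4 of 4 hypoxia arrays. Against normoxia, chronic hypoxia gave 13 calls, all higher, for 9 genes. Hk2 rose by 2.69 (adjusted p = 0.00911), Ak4 by 4.03 (0.0145), Bnip3 by 2.41 (0.0191), Slc2a1 by 2.27 (0.0287), and Sap30, a part of the Sin3 corepressor, by 2.21 (0.0308). The remaining calls were Pdk1 (2.08, with 2.05 and an adjusted p of 0.0962 at its brighter probe set), the lipid droplet protein Hilpda (1.90), the stress transcription factor Ddit3 (1.82) and the arginine demethylase and lysyl hydroxylase Jmjd6 (1.82). Cyclic hypoxia against normoxia gave 0 calls in limma, with 2024 probe sets at an unadjusted p under 0.05 (1321 of them lower), where 678 are expected by chance. The smallest adjusted p there was 0.0575, for the linker histone H1f2 (2.11), followed by 0.0747 for genes that include the splicing factor Srsf5 (1.76), the cold-inducible RNA-binding protein Cirbp (1.96), Mt2 (1.31), and, lower, the RNA-binding protein Tardbp (-1.65) and Luc7l2 (-2.09).

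These counts depended on single arrays and on the moderation. The 13 chronic calls became 3 without the array after chronic hypoxia and reoxygenation, 5 without that after chronic hypoxia, and 65 or 70 without either cyclic array, and 0 without the intensity trend or without the filter. The 0 cyclic calls became 20 with quantile normalization (chronic 21), 158 with median centring (chronic 31) and 1268 without the array after cyclic hypoxia.

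At the end of hypoxia alone, the interaction fit called 8 probe sets higher and 2 lower. Hk2 rose by 2.32, Ak4 by 3.21, Mt2 by 1.51, Bnip3 by 2.02, Slc2a1 by 2.07, and Ero1a, an oxidase of protein folding in the endoplasmic reticulum, by 2.15. Fam120a rose by 3.75 at a dim probe set with 1.70 units in normoxia, below the floor, while its brightest probe set gave -0.06 and 0.01. Cnn3 fell by 2.14 on the log2 scale at 1 probe set, while its brightest gave -0.01 and 0.10. The second lower probe set, which names 2 genes, fell by 2.71. Without the trend or the filter the count was 0. On simulated data this fit made 31 false calls per data set. Those data held 200 changed probe sets each and gave many true calls as well, so that number does not carry over to the calls here.

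In the additive fit of mean hypoxia, the unfolded protein and integrated stress response had a median of 0.50 over 28 genes (camera adjusted p = 1.13e-15, and adjusted p = 0.137 with an estimated correlation). With p adjusted over the list alone 14 members rose and 0 fell, against 0 over all probe sets. Trib3, a pseudokinase induced by ATF4, rose by 1.48, Herpud1 by 1.34 and Ppp1r15a, which restores translation after stress, by 1.39. The NRF2 and antioxidant list had a median of 0.26 (camera adjusted p = 1.17e-05, and adjusted p = 0.164 with an estimated correlation), and 5 of 16 members rose adjusted over the list alone. Hmox1, heme oxygenase, rose by 1.45, and Gclm, which takes part in glutathione synthesis, by 0.76.

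For the HIF lists the same test gave medians of 0.49 for glycolysis (camera adjusted p = 6.89e-15, and adjusted p = 0.187 with an estimated correlation) and 0.75 for the other targets (4.12e-18, and adjusted p = 0.137 with an estimated correlation). Adjusted over the list alone, 12 glycolysis members rose and 0 fell, and 18 of the other targets rose and 1, the transferrin receptor Tfrc, fell. Over all probe sets the calls were 1 and 1. No camera call in any of the 4 contrasts held with an estimated correlation. That version of the test takes its degrees of freedom from the fit, 2 here, so hardly any list could pass. The stress response lost its call at an estimated correlation of -0.0008, below the preset 0.01. The loss by itself therefore does not show that correlation between genes made the calls. For some other lists the estimates were well above the preset value. They were 0.27 for glycolysis, 0.37 for demethylases, 0.31 for oxidative phosphorylation and 0.14 for NF-kB genes. At such correlations the p-values of these lists at the preset value would be too small. By fry, which asks only whether a list's genes move in the same direction on balance, glycolysis (adjusted p = 0.0417), other HIF targets (0.0237), the stress response (0.0315), NRF2 genes (0.0237), melanocyte genes (0.0237) and cell cycle genes (0.0432) passed for mean hypoxia. Immediate-early genes (0.242), demethylases (0.271), NF-kB genes (0.103) and housekeeping genes (0.0641) passed camera at the preset correlation but not fry.

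Immediate-early genes had a median of 0.33 in mean hypoxia (camera adjusted p = 6.64e-06, and adjusted p = 0.255 with an estimated correlation), with 3 members higher and 1 lower adjusted over the list alone. At the end of hypoxia their median was 0.55 after chronic hypoxia, with 10 of 28 at least 2-fold higher, and -0.01 after cyclic hypoxia, with 1 (percentile 68.7). For cyclic hypoxia alone camera did not pass (adjusted p = 0.0554). Cell cycle genes had a median of -0.35 (2.44e-06, and adjusted p = 0.164 with an estimated correlation), with 0 calls adjusted over the list alone. For cyclic hypoxia alone (median -0.39, 9.08e-06, and adjusted p = 0.207 with an estimated correlation) 9 members fell and 1, Aurka, rose adjusted over the list alone, with Tyms at -2.88, Ccne2 at -2.87 and Bub1 at -1.51. At the end of hypoxia the replication licensing factor Cdc6 differed by -1.07 and -1.50, and cyclin E1 (Ccne1) by -0.81 and -0.67. Oxygen-dependent histone demethylases had medians of 1.27 after chronic and 0.55 after cyclic hypoxia at the end, and 0.28 in the fit (0.00562, and adjusted p = 0.350 with an estimated correlation). Adjusted over the list alone, 4 of 10 rose, Jmjd6 by 1.37, Kdm3a by 1.34, Kdm4b by 0.92 and Kdm5b by 0.78. Kdm3a and Kdm4b also belong to the list of other HIF targets, so this result is in part the same. After the last hour the median was 0.50 for chronic and -0.20 for cyclic hypoxia, the latter with 0 members 2-fold higher and 3 lower, and 0.41 among members with a mean signal of at least 100. Over the last hour of the cyclic regime 0 of 10 were above 0 (median -0.66), and the fit of cyclic hypoxia gave -0.08. Melanocyte and pigment genes had a median of 0.19 (0.000399, and adjusted p = 0.187 with an estimated correlation). Adjusted over the list alone 5 rose, among them Dct by 0.29, and Mitf, the master regulator of the lineage, fell by 0.72 on the log2 scale. The fit gave Mitf 0.02 for chronic and -1.46 for cyclic hypoxia. Rab27a, a melanosome transport GTPase, also rose by 0.97, while another of its probe sets gave -0.12 and -0.69 at the end of hypoxia. The pigment genes Tyr and Pmel differed by 1.11-fold and 1.19-fold in size between chronic hypoxia and normoxia.

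NF-kB and inflammatory genes had a median of 0.33 (0.00562, and adjusted p = 0.277 with an estimated correlation), with 2 of 8, Relb and the chemokine Cxcl10, higher adjusted over the list alone. Without the filter its median after chronic hypoxia changed sign, from 0.52 to -0.27. Housekeeping genes had a median of 0.09 (0.0334, and adjusted p = 0.277 with an estimated correlation) and 0 calls adjusted over the list alone; their medians of 0.10 after chronic hypoxia, and after cyclic hypoxia with reoxygenation, turned to or below 0 with quantile normalization. The camera test did not pass for heat shock chaperones (median -0.13, adjusted p = 0.0689), invasion and metastasis genes (0.07, 0.0979), angiogenic factors (0.06, 0.0809), oxidative phosphorylation (0.04, 0.0689), sterol synthesis (-0.06, 0.241), interferon-stimulated genes (-0.22, 0.222) or p53 targets (-0.07, 0.198). For cyclic hypoxia alone heat shock chaperones (median -0.25, adjusted p = 0.0185, and adjusted p = 0.297 with an estimated correlation) and oxidative phosphorylation (0.06, 0.0223, and adjusted p = 0.575 with an estimated correlation) did pass. Neither passed by fry there (adjusted p = 0.0791 and 0.414). In mean hypoxia p53 targets had 2 members lower adjusted over the list alone, Mdm2 and Trp53inp1, and the other lists that did not pass had 0. Another probe set of Trp53inp1 gave 0.13 after cyclic hypoxia, where the brightest gave -1.43.

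Between cyclic and chronic hypoxia limma made 0 calls, so the genes that differed most at both collections are given as values. Ak4 was lower after cyclic hypoxia by -2.22 at the end and -2.99 after the last hour, and Fos, an AP-1 subunit, by -2.54 and -1.64. Rora, a nuclear receptor of the circadian clock (-1.78 and -2.97), Ccnt2, a cyclin of transcription elongation (-2.08 and -2.01), Klf7 (-1.64 and -1.72) and Hs3st1, a heparan sulfate sulfotransferase (-1.54 and -1.56), were also lower. Higher after cyclic hypoxia were H1f2 (1.46 and 1.69), Osgin1 (an oxidative stress response gene; 1.41 and 1.51), the iron exporter Slc40a1 (1.40 and 1.35), Cirbp (1.18 and 1.16), the thioredoxin reductase Txnrd1 (1.04 and 1.26) and the monoacylglycerol lipase Mgll (1.49 and 1.03). The last hour's values rest on the array that stood furthest from the others.

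Other HIF targets had a median of -0.62 for cyclic against chronic hypoxia in the additive fit (camera adjusted p = 4.27e-05, and adjusted p = 0.472 with an estimated correlation). Adjusted over the list alone 12 of 31 were lower, among them Hilpda by -1.65, Ero1a by -2.01, Mxi1 (a MYC antagonist) by -1.64, Ddit4 by -1.58 and Vegfa by -1.15, and 1, the lipid droplet protein Plin2, higher by 0.70. For glycolysis the median was -0.26 (0.0286, and adjusted p = 0.664 with an estimated correlation), with 3 lower adjusted over the list alone. These were the lactate exporter Slc16a3 by -1.64, Hk2 by -1.19 and Slc2a1 by -0.99. NRF2 genes had a median of 0.09 (0.0286, and adjusted p = 0.472 with an estimated correlation), and 3 were higher adjusted over the list alone, Osgin1 by 1.46, Txnrd1 by 1.15 and Srxn1 (sulfiredoxin) by 0.84. Between single arrays the NRF2 medians, 0.09 at the end and 0.22 later, lay within the range of the random lists (percentiles 87.7 and 92.2). Immediate-early genes had a median of -0.55 (0.0207, and adjusted p = 0.547 with an estimated correlation). Adjusted over the list alone, Fos (-2.09), the matricellular Ccn1 (-1.87) and Nr4a1 (-1.02) were lower and the kinase Sgk1 (1.57) higher.

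Another 4 lists passed camera at the preset correlation in this contrast. They were demethylases (median -0.64, 0.00628, and adjusted p = 0.547 with an estimated correlation), heat shock chaperones (-0.40, 0.0286, and adjusted p = 0.472 with an estimated correlation), cell cycle genes (-0.20, 0.0350, and adjusted p = 0.472 with an estimated correlation) and oxidative phosphorylation (0.04, 0.0398, and adjusted p = 0.708 with an estimated correlation). By fry no list passed in this contrast, those of HIF targets included (smallest adjusted p = 0.0655). Over all probe sets limma made 0 calls, with 1960 probe sets at an unadjusted p under 0.05, 1421 of them lower, and a smallest adjusted p of 0.127. Leaving out the array after cyclic hypoxia gave 1333 calls, and leaving out either normoxia array 72 or 63. By size alone, 95 genes were 2-fold higher and 291 lower at the end, and 194 higher and 975 lower 1 h later (359 and 798 with quantile normalization, 361 and 732 with median centring). Among genes with a mean signal of at least 100 these were 5 and 36 at the end, and 18 and 334 later. Both collections, which share no array here, agreed at 19 higher and 101 lower genes and were opposite at 20, where independent calls would give 2.38 and 36.6.

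After 1 h of reoxygenation, HIF targets still stood above normoxia. Hk2 differed from normoxia plus 1 h by 2.43 after chronic and 1.30 after cyclic hypoxia, Bnip3 by 2.16 and 1.57, and Slc2a1 by 1.72 and 0.78. Vegfa differed by 2.48 and 0.77, Ddit4 by 2.38 and 0.18, and the clock repressor Bhlhe40 by 2.45 and 0.48. Other HIF targets had medians of 0.85 and 0.41, with 13 and 5 of 31 at least 2-fold higher, and glycolysis 0.52 and 0.44, with 5 and 2 of 18. Immediate-early genes had medians of 0.70 and 0.37 (percentiles 100 and 99.95), and 11 and 7 of 28 at least 2-fold higher. Ccn1 differed by 2.80 and 1.60 and the zinc finger factor Egr1 by 1.40 and 3.24.

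Others high in both arrays were Trib3 (1.59 and 1.60), Ppp1r15a (1.55 and 1.45), Rassf1 (1.76 and 1.44), Rusc2 (1.69 and 1.44), Sugp2 (1.77 and 2.06) and Hip1r (1.52 and 1.39, with -0.11 and -0.62 at another probe set). The lowest included Txnip, an inhibitor of thioredoxin and of glucose uptake (-2.77 and -1.49), the TGF-beta-induced repressor Klf10 (-1.47 and -1.94) and the inducible HSP70 Hspa1b (-1.81 and -1.28). Slc7a7 (-1.40 and -1.18), Zmynd19 (-1.10 and -1.20), Nrep (-1.14 and -0.98), Cklf (-0.93 and -0.95), Ttpa (-0.91 and -3.10) and Ecpas (-0.90 and -0.89) followed. Macir (-1.09 and -1.31, with 0.02 after chronic hypoxia at another probe set) differed by 1.34 between the normoxia arrays. Mitf differed by -0.21 after chronic and -2.02 after cyclic hypoxia, and Hif1a by 0.50 and -1.39.

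Counts at this collection were 231 higher and 87 lower after chronic hypoxia (177 and 119 with quantile normalization) and 276 higher and 821 lower after cyclic hypoxia. For the latter, median centring gave 427 and 621 and moved the median of all genes by 0.19, and quantile normalization gave 367 and 708. With no filter the counts were 1357 higher and 1268 lower, so the direction turned. Among genes with a mean signal of at least 100 the counts were 38 higher and 2 lower, and 35 higher and 272 lower. In the cyclic array lower genes grew in number with genomic length, from 54 of 1549 genes in the shortest of 5 length groups to 294 of 1548 in the longest (Spearman's rho -0.244 across genes). Both arrays were 2-fold higher at 101 genes, lower at 16 and opposite at 13. Independent calls would give 8.23 and 9.22 and a shared control alone 29.4 and 31.0. The covariance was 0.08, against 0.07 simulated, and the correlation across genes 0.25, against 0.50 simulated. The 16 lower genes were fewer than a shared control alone would give, so their overlap shows no effect common to both regimes. The 101 higher genes were more than it would give, though part of that overlap may come from the shared control.

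**Figure D4:**
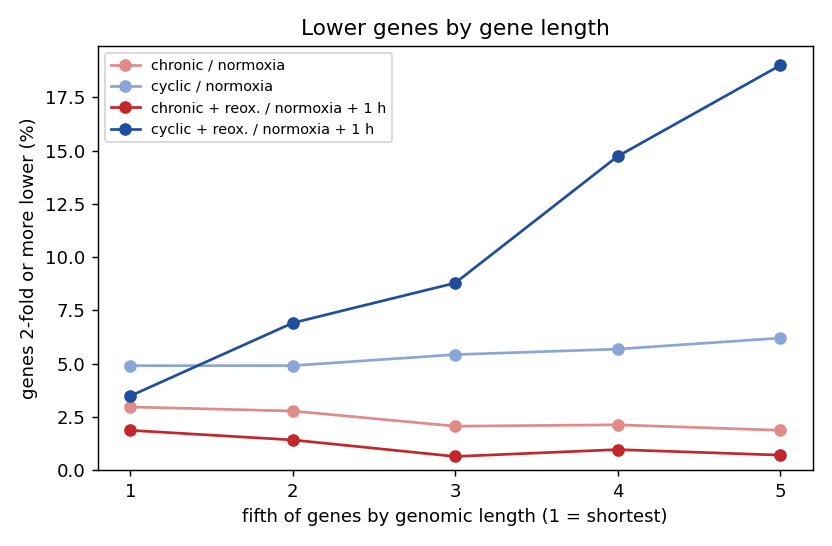
Percent of genes 2-fold or more lower than the normoxia array of the same collection, in 5 groups of genomic gene length, for the 4 hypoxia arrays (1 array per line). Only the line for cyclic hypoxia with reoxygenation climbs steeply, from 54 to 294 genes.

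Few genes differed 2-fold the same way over the last hour after both regimes. Gtpbp2, high at the end of hypoxia, differed by -1.80 after chronic and -1.22 after cyclic hypoxia over the hour. Lower too were Hmga2 (an architectural chromatin protein; -1.15 and -0.85), Bzw2 (-0.88 and -0.83), Def8 (-1.07 and -0.82), Gigyf2 (-0.82 and -1.15) and the nuclear RNA Malat1 (-0.88 and -3.78). Tnrc6a (-1.13 and -0.94) and Rbfox2 (-1.02 and -0.79) were also lower, but after chronic hypoxia other probe sets gave 0.06, 0.32 and 0.38 for Tnrc6a and 0.25 for Rbfox2. Higher were the clock gene Per1 (1.07 and 1.61), Sugp2 (1.34 and 1.22), Septin10 (3.46-fold and 2.30-fold), Arap1 (0.87 and 1.36), Hint3 (1.70 and 0.81) and Rgcc (0.80 and 1.10). Map3k12 (1.26 and 1.33) and Ddr1 (1.15 and 1.06) were higher as well, but after cyclic hypoxia other probe sets gave -0.26 and -0.26 for Map3k12 and -0.39 and -0.92 for Ddr1. Another of Ddr1 gave -2.68 after chronic hypoxia. Pdk1 differed by -0.95 and -0.63 over the hour and Hk2 by -0.53 and -0.40.

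Over the hour 172 genes were 2-fold higher and 112 lower after chronic, and 225 and 579 after cyclic hypoxia (356 and 385 with median centring). Among genes with a mean signal of at least 100 they were 11 and 6, and 9 and 218. Both agreed at 32 higher and 11 lower and were opposite at 26, where independent calls would give 5.00 and 8.37, with a correlation across genes of 0.06. A return was read in the regime that did not serve to choose the genes, among 2-fold genes with both signals above the floor and the higher at or above 35.8 units. The 95 such genes higher at the end of cyclic hypoxia had a median of -0.19 over the last hour in the chronic arrays, 67 of them below 0, and the 200 lower had 0.23, 150 of them above 0. The 104 higher at the end of chronic hypoxia had a median of -0.10 in the cyclic arrays, 60 of them below 0, and the 60 lower had 0.10, 36 of them above 0. The interaction fit called 2 probe sets whose hypoxia effect changed in the last hour. Ifngr2, a chain of the interferon-gamma receptor, rose by 5.32 (SE 0.650, adjusted p = 0.0206) at a probe set with 1.64 units, below the floor, in normoxia plus 1 h, while its brighter probe set gave 0.09 and 0.19 at the end and -0.25 and -0.23 later. The second, naming 2 genes, rose by 3.99 (adjusted p = 0.000941). Both calls rest on 1 normoxia array, and without the trend or the filter the count was 0.

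The series title raises metastasis, for which a list of 39 invasion genes was fixed. Of these, 34 were on the array and 20 passed the signal filter, so the dimmer members are not covered. Of 20 measured, 1 was 2-fold higher after chronic hypoxia and 0 after cyclic hypoxia at the end, with medians of 0.08 and 0.15 and 0 lower. After the last hour 0 were higher and 1 lower after chronic hypoxia (median 0.26, percentile 99.8, 16 of 20 above 0), and 1 higher and 4 lower after cyclic hypoxia (0.12, percentile 73.7). Cyclic against chronic hypoxia had 1 higher and 1 lower at the end and 1 higher and 4 lower later. Nes, an intermediate filament of neural progenitors, was the high member after chronic hypoxia (2.48), but it also differed by 2.03 between the normoxia arrays and gave -0.45 at its other probe set. Plaur, the urokinase receptor, differed by 0.56 and 0.86, and Cdh2 (N-cadherin) by -0.47 and -0.77. After the last hour Fn1 (fibronectin) differed by 0.65 and 0.60, Timp1 by -1.02 and -0.27 and Timp3 by -0.17 and -1.03 (2.18 at another, dim probe set). Adjusted over the list alone, Mmp2, a gelatinase, was higher by 1.36 for cyclic against chronic hypoxia, and Zeb2 (-1.40) and Nes (-2.91) lower, though after the last hour the other Nes probe set gave 0.74 in this contrast. The camera test of the list in that contrast did not pass (adjusted p = 0.988; median -0.02 with direction up). Angiogenic factors, of which 7 of 16 on the array passed the filter, had medians of 0.00 and 0.13 at the end and 0.53 and 0.12 later. The first turned to -0.02 with quantile normalization.

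Of the markers of other cell types, 0 of 8 fibroblast and 0 of 5 endothelial genes passed the signal filter, with highest mean signals of 5.55 and 4.23 units. Of 7 immune markers on the array 4 passed, led by Cd68 at 34.6 units. After cyclic hypoxia and reoxygenation, the array that stood furthest from the others, these 4 had a median of 0.83 (percentile 96.9), with 4 above 0 and 2 at least 2-fold higher. The latter were Lyz2 (1.70, and 1.81 after chronic hypoxia and reoxygenation), at 3.46 units in normoxia plus 1 h, and Adgre1 (1.15), at 7.14 units there. Among 4 keratinocyte markers 1 passed, Krt5, at a mean of 10.0 units.

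The normoxia arrays differed most at dim genes. Neat1, a nuclear RNA, was higher by 1.91 after the extra hour, Mdfi by 1.41, Macir by 1.34 (-0.59 at another probe set) and Siah1a by 1.30 (-0.13 and -0.12 at others). P2rx3 (-1.61), Hip1r (-1.38), Lztr1 (-1.30) and Map3k12 (-1.24) were lower, with 0.37 for Hip1r and 0.71 and 0.15 for Map3k12 at other probe sets. The central 95% of differences ran from -1.44 to 1.09 for 1995 genes under 35.8 units, and from -0.44 to 0.43 for 3159 genes of 100 to 1000 units.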

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

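The limits that single out opposite genes here were set after the data were seen, as were the tests of scaling, dim probe sets, 5' degradation and hybridization and the slope of signals, and the choice of these patterns.

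The interaction test of a hypoxia effect that differs between collections called 2 probe sets. That of Ifngr2 (5.32, adjusted p = 0.0206) had 1.64 units in normoxia plus 1 h, below the floor, so its size rests on the floor, and the brighter Ifngr2 probe set had no such change (0.09 and 0.19 at the end, -0.25 and -0.23 later). A probe set naming 2 genes (3.99, adjusted p = 0.000941) rests on a normoxia signal of 2163 units, against 330 in normoxia plus 1 h. Hspa1b, at the end of hypoxia, was higher after chronic hypoxia (2.30) and lower after cyclic hypoxia (-1.04), and this difference was not tested. Ogt, the O-GlcNAc transferase, was opposite 1 h later (1.56 after chronic and -1.32 after cyclic hypoxia), and so was Myc (1.11 and -1.38), neither of them tested. Control probe sets outside the comparisons also differed between arrays, since poly-A spike-ins had a median log2 ratio to normoxia of 0.91 after cyclic hypoxia and 1.11 after cyclic hypoxia and reoxygenation, above 0.30 to 0.45 in the other 3 arrays.

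Among genes that pass the filter, more were lower than higher after cyclic hypoxia and reoxygenation, 2.97 lower for each higher, but with no filter 1357 were higher and 1268 lower, so the pattern holds only without the dimmest genes. The ratio was 1.93 with quantile normalization and 1.45 with median centring, and 7.77 among genes with a mean signal of at least 100, where it stayed at 3.34 or more under both scalings, which argues against scaling or dim probe sets as the whole cause. Removing the trend on gene length left a ratio of 2.36, with 689 of 819 lower genes still lower, so an even shift with length accounts for a part at most. The removal takes out only the average shift at each length. A loss that strikes some long genes and spares others would remain, so a larger part for length is not excluded. RNA degraded from the 5' end stays open, since the 3' over 5' ratio of the beta-actin control was 1.17, lower than in each other array (at most 1.25), and that of Gapdh (0.845) lay inside their range; control ratios from 1 array cannot decide it. A loss of RNA in the cells, as the regime itself might bring, was not tested and rests on this array alone.

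Poly-A spike-ins, which are added to the RNA before labelling, were higher in both cyclic arrays. They were dim, with a middle range of 23.4 to 68.2 units in normoxia, where the median signal of the array was 18.8. Whether these signals stood above background was not tested. Hybridization spike-ins, added after labelling, reached only 0.0943 in the same arrays, which argues against array scaling or hybridization. Gene probe sets of the same brightness had medians of -0.0631 and -0.11 in these arrays, which argues against a general rise of dim signals. A smaller share of messenger RNA in the total RNA of cyclic cells, or a difference in the amount of spike-in added, could give this pattern; neither was tested.

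HIF targets were less raised by cyclic than by chronic hypoxia at the end, with a median difference of -0.59 over 49 genes, 38 of them lower. Members shorter than the median gene had -0.54, and longer members -0.62. The bootstrap range of the shorter ones, -1.05 to -0.14, was drawn over genes and leaves out the spread between arrays. Across all genes this contrast showed no trend on length (Spearman's rho -0.005). There was thus no loss growing with length here for this test to exclude. A compressed signal range of the cyclic arrays made a prediction for the lists other than those of HIF. None of them would be at least 0.1 higher after cyclic hypoxia at both collections. There were 0 such lists (NRF2 genes came nearest, by 0.09 and 0.18), so this count, written beforehand, went with compression. The same prediction named the SD across all genes of the difference from normoxia at the end. It was 0.570 after cyclic and 0.503 after chronic hypoxia, which went against compression. The slope on normoxia of genes with a mean signal of at least 100 was a test added after that count. It was 0.972 after cyclic and 0.971 after chronic hypoxia, and 1.045 and 0.996 with reoxygenation. These slopes argue against compression of these brighter genes. The list count goes one way and the SD and slopes the other, from single arrays, so compression is not excluded. A weaker HIF response under interrupted hypoxia may be considered only as a hypothesis. At the end, cyclic cells had been hypoxic for 1 h since their last reoxygenation, and chronic cells for 3 h. The cyclic regime also lasted longer in total. These differences cannot be told apart from the interruption itself.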

How the results depend on the processing

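Counts of calls, of genes between each hypoxia array and normoxia or between the normoxia arrays, and of genes on which both regimes or collections agree are listed here wherever an alternative moved them by more than 1.5 times, and with 1 array left out as a range. Of the single genes, list medians and list tests, 6815 values stayed within the limits set for them, 291 moved beyond these and are not listed one by one, and 30 reversed. All 35 list calls were lost with an estimated correlation, and 20 of them with fry. The first loss says little about correlation, since that test had only 2 residual degrees of freedom. Genes with a mean signal of at least 100 and the removal of the length trend were chosen after seeing the data, and the other alternatives before. No paired analysis was possible because the labels give no replicate numbers; arrays are matched only by collection, which the additive fit holds as a term. Signal over background limits the dim genes, where single arrays differ 2-fold by noise. Unless stated, the cause was not tested.

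With no filter, higher and lower genes were 767 and 935 after chronic hypoxia, 613 and 1250 after cyclic hypoxia, 1070 and 608 after chronic hypoxia with reoxygenation, 1357 and 1268 after cyclic hypoxia with reoxygenation, and 521 and 988 between the normoxia arrays. Both arrays agreed at 201 and 506 genes at the end, 466 and 250 after reoxygenation, 145 and 230 for cyclic against chronic hypoxia and 232 and 92 over the last hour. With the filter at the 60th percentile these were 87 and 42, 76 and 148, 71 and 14, 79 and 540, and 3 and 12, and for both arrays 21 and 22, 19 and 3, 7 and 48, and 2 and 1. With a mean signal of at least 100 they were 52 and 14, 37 and 52, 38 and 2, 35 and 272, and 0 and 1, and for both arrays 15 and 7, 10 and 2, 3 and 20, and 1 and 1.

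With the floor at the 40th percentile, agreement was 41 higher at the end, 42 after reoxygenation, 11 for cyclic against chronic hypoxia and 11 higher and 3 lower over the last hour. Lower genes were 116 after chronic hypoxia and 40 after its reoxygenation, and the normoxia arrays differed at 33 and 71. With a pseudocount, agreement was 66 higher after reoxygenation, 11 for cyclic against chronic hypoxia, and 19 and 6 over the last hour, with 44 higher between the normoxia arrays. Median centring gave 427 higher after cyclic hypoxia and reoxygenation.

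Calls in the additive fit were 2 for mean hypoxia, 13 for chronic, 0 for cyclic and 0 for cyclic against chronic hypoxia, and in the interaction fit 10 at the end and 2 for the change in the last hour. Quantile normalization gave 24 for mean hypoxia, 21 for chronic, 20 for cyclic, 41 at the end and 4 for the change. Median centring gave 35, 31 and 158, then 32 for cyclic against chronic hypoxia, 74 at the end and 20 for the change. Without trend the counts were 0 for mean hypoxia, chronic hypoxia, the end and the change, and likewise 0 for these 4 with no filter. The 60th percentile filter gave 1 for mean hypoxia, 4 at the end and 1 for the change. The floor at the 10th percentile gave 1 for mean hypoxia and 4 at the end, that at the 40th percentile 1 for cyclic hypoxia, 6 at the end and 1 for the change, and the pseudocount 4 at the end and 1 for the change. A mean signal of at least 100 gave 10 for mean hypoxia, 1 for cyclic hypoxia and 17 at the end. Leaving out the collection term gave 7 for mean and 3 for cyclic hypoxia, and robust moderation 1 for cyclic hypoxia.

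With 1 array left out, whose remaining partner is then assumed to vary like the other groups, mean hypoxia had 4 (without normoxia) to 518 calls (without cyclic hypoxia), and 57 without cyclic hypoxia and reoxygenation. Chronic hypoxia had 3 (without its reoxygenation array) to 70 (without cyclic hypoxia and reoxygenation), cyclic hypoxia 4 (without normoxia plus 1 h) to 1268 (without cyclic hypoxia), and cyclic against chronic hypoxia 0 (without chronic hypoxia) to 1333 (without cyclic hypoxia). The 2 calls of mean hypoxia and the 13 of chronic hypoxia kept their sign in each case.

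Reversals, counted for genes that differed at least 2-fold and for list medians of at least 0.3, came from other probe sets of a gene, except for the NF-kB list after chronic hypoxia with no filter (-0.27). Smaller list medians also changed sign, 29 values in all with that 1. With median centring, 1 h after cyclic hypoxia, sterol synthesis went from -0.12 to 0.07, interferon-stimulated genes from -0.17 to 0.0196 and p53 targets from -0.14 to 0.05. With a mean signal of at least 100, demethylases at that collection went from -0.20 to 0.41 and interferon-stimulated genes from -0.17 to 0.10, and after chronic hypoxia interferon-stimulated genes from -0.24 to 0.15 and cell cycle genes from -0.22 to 0.00184. At the end of hypoxia other probe sets gave -0.45 for Nes, -0.12 and -0.12 for Rab27a after chronic hypoxia, and -0.69 for Rab27a, 0.30 for Sgms1 and 0.13 for Trp53inp1 after cyclic hypoxia. After reoxygenation they gave -0.11 and -0.62 for Hip1r and -0.66 and -0.17 for Sesn2 (chronic and cyclic), 0.0193 for Macir and -0.81 for Rab27a (chronic), 2.18 for Timp3 (cyclic) and 0.74 for Nes (cyclic against chronic). Over the last hour they gave -2.68 for Ddr1, 0.0610, 0.32 and 0.38 for Tnrc6a and 0.25 for Rbfox2 after chronic hypoxia, and -0.39 and -0.92 for Ddr1 and -0.26 and -0.26 for Map3k12 after cyclic hypoxia. Between the normoxia arrays they gave 0.37 for Hip1r, -0.59 for Macir, 0.71 and 0.15 for Map3k12 and -0.13 and -0.12 for Siah1a.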

Other observations

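The choice of the genes and lists in this part, but not the count of other normoxia choices, was made after the result was seen.

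Genes of the unfolded protein and integrated stress response stood above normoxia 1 h after both regimes, as values without a test. Their list had medians of 0.34 after chronic and 0.53 after cyclic hypoxia with reoxygenation, against 0.48 and 0.31 at the end of hypoxia. Nupr1, a stress-induced chromatin protein, differed by 1.26 and 1.40, and Sesn2, which restrains mTORC1 under amino acid shortage, by 1.28 and 1.57, but Sesn2 also differed by -1.11 between the normoxia arrays and another of its probe sets gave -0.66 and -0.17. The cystine transporter Slc7a11 differed by 0.14 and 1.12. In the additive fit of cyclic hypoxia against normoxia, 12 of 28 members rose adjusted over the list alone, Xbp1 by 0.81 and Hspa5 (BiP) by 0.62, and Hsp90b1 fell by 0.83 on the log2 scale, while its other probe set gave 0.86 at the end of cyclic hypoxia and -1.70 later.

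Between single arrays the heat shock list had its lowest median, -0.29, after cyclic hypoxia and reoxygenation, with 6 of 18 members at least 2-fold lower, among them the co-chaperone Chordc1 (-2.53) and Hsph1 (-1.49). Irf7, an interferon regulatory factor, differed by -0.64 and -2.33 at the end of hypoxia and by 2.63 and 1.23 later, and by -1.81 between the normoxia arrays. The DNA synthesis gene Tyms differed by -1.47 and -3.41 at the end.

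Of the 9 choices of 1 array per collection as normoxia, 2 gave at least as many calls for mean hypoxia in the additive fit as the 2 of the real choice, itself included. The highest other count was 7, with the 2 chronic arrays taken as normoxia. So few choices cannot give a share under 0.05.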
